A study of Mus musculus with 19 samples.

How the data were processed

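RNA was measured in 19 organoid lines grown from mouse pancreatic ductal cells. Organoids are cultures in which epithelial cells embedded in a basement membrane gel grow as hollow spheres. Of these lines, 7 came from ducts of histologically normal wild-type pancreas. Another 6 came from ducts of pancreas with pancreatic intraepithelial neoplasia (PanIN), a precursor lesion of ductal adenocarcinoma. The remaining 6 came from adenocarcinomas of mice that carried a Cre-activated Trp53 R172H allele. Per the labels, all mice had a C57B6/J background, 11 lines were female and 8 male, and every line was kept in the same medium with EGF, FGF-10, noggin, R-spondin, gastrin and a TGF-beta receptor inhibitor. Per the labels' protocols, total RNA was extracted with Trizol from several wells per line and made into strand-marking libraries after removal of ribosomal RNA. The labels give each line a number of its own within its group and do not say whether any lines shared a mouse or litter, so p-values measure the spread between lines.

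The authors deposited 1 table with 29861 rows that holds TPM, a transcript abundance scaled to the same total in every library, for each line. Per the submitters' processing notes, RSEM 1.2.11, Bowtie 1.1.0, FastQC and genome build mm9 were used; the gene annotation is not given in the sources used here. Each TPM column of the deposited table sums to 1000000 within rounding. The table also gives the authors' own comparisons per gene: the mean signal over all lines (per the file headers a base mean of DESeq output), the authors' log2 fold change with its standard error, the authors' test statistic (a score per gene) and the authors' p-value and adjusted p-value. Per the submitters' processing notes, DESeq2 1.4.1 and DESeq were used. The deposited table gives no such comparison for 11 expressed rows, several of them with names of mitochondrial transcripts. These 11 rows took 16.3% to 28.6% of the TPM of a line, and a single row took 12.4% to 22.2%. The number of columns that belong to other samples is 0.

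TPM keeps no depth, so the number of reads behind each value is unknown and no counting interval is given. Count models, which had been planned in case counts were present, were not run. Values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3: one mean per group was fitted over all 19 lines, contrasts were tested with eBayes (trend), two-sided, and p-values were adjusted by Benjamini-Hochberg within each contrast. A gene was tested when its TPM was at least 1 in at least 6 lines (12500 genes) and called when its adjusted p was below 0.05. Folds are on the log2(TPM + 1) scale, which understates the change of low genes. Group values are mean TPM ± SD. Tables were read with data.table (version 1.17.8) and jsonlite 2.0.0, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

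A set of 33 gene lists was fixed before the data were examined, together with the design, the thresholds, the rule for naming genes and most alternatives. The nucleoporin list was included with the study's interest in these genes already known. Lists with at least 5 tested members (25 lists) were tested in each contrast with camera (preset correlation 0.01), adjusted over lists and the 3 contrasts, and the test was repeated with an estimated correlation and with fry. Of the 31 list calls made by camera, 1 held with an estimated correlation, that of the p53 targets between tumor and PanIN lines. Other splits of the lines gave 8 to 36 camera calls, so a camera call alone does not argue against chance. Numbers of members that rose or fell are given over all genes tested and also adjusted over the list alone. A list score is the mean log2(TPM + 1) over the tested members, minus the mean of the 19 lines.

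The naming rule took, per contrast, up to 10 genes with the largest rise and up to 10 with the largest fall, among called genes with a mean TPM of at least 5 in the higher group and with every line of one group above every line of the other. It also took up to 4 members of each list with the smallest p and all genotype genes. Symbols of predicted genes were left out, and so were transcripts named only by a sequence identifier. Some alleles of these mice and some genes that this rule selects are not reported here. Where other genes are named, this is said beside them.

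The column names of the deposited table carry library identifiers of 3 series, which are treated here as a possible batch. The first series holds normal 5, 6 and 7, PanIN 1, 2 and 3 and tumor 4. The second holds normal 10 and 11, PanIN 4 and tumor 5, 7 and 8, and the third holds normal 12 and 13, PanIN 5 and 6 and tumor 3 and 9. Genes for the sex check (Xist and 4 Y-linked genes) matched the labelled sex in all 19 lines. Chromosomes were taken by gene symbol from a RefSeq gene table of another build and used only to group genes.

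The tests were tried on simulated data: 5 sets of 12500 genes with 200 changed genes each. At a log2 change of 1, the fit recovered 94.0% of the changed genes for PanIN vs normal, 91.6% for tumor vs normal and 91.0% for tumor vs PanIN. At a log2 change of 0.5, the shares were 64.8%, 66.0% and 60.9%. False genes made up 5.79%, 5.61% and 4.95% of the calls. The simulated genes varied independently of each other. Genes of the real lines moved together, with an estimated correlation of 0.87 among cell cycle genes. These shares are therefore not error rates of the real calls. Alternatives covered pseudocounts of 0.1 and 5, other filters, 2 other scalings, a 2-fold minimum, fits of only 2 groups, sex as a covariate, a block for the line number, weights per line and leaving out each line in turn. After the data were seen, the identifier series as a covariate, a rescaling without the 11 rows and a fit without normal 11 and PanIN 6 were added.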

Results

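The data comprised RNA-seq profiles of 19 mouse pancreatic ductal organoid lines: 7 normal lines, 6 PanIN lines and 6 tumor lines. The 3 comparisons asked how expression differed between PanIN lines and wild-type normal lines, between tumor lines and normal lines, and between tumor and PanIN lines, which differed in the Trp53 allele and in the tissue of origin. Between 11938 and 12437 genes reached a TPM of 1 in each line. Depth was unknown because TPM keeps none.

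The first principal component held 41.9% of the variance and the second 12.4%. All 7 normal lines lay at -9.88 or below on the first component. PanIN 1 to 4 lay between -15.9 and -4.53, PanIN 5 at 12.1 and PanIN 6 at 30.4. Among the tumor lines, tumor 5, 8 and 9 lay between 37.6 and 45.7, while tumor 4 lay at 0.0913, tumor 3 at 11.8 and tumor 7 at 16.4. PanIN 6 was thus farther along this component than 3 of the 6 tumor lines. The third component held 9.70% and went in part with the identifier series. On it, first-series normal lines lay at -10.5 or below and the other normal lines at 9.24 or above. First-series PanIN lines lay at -2.37 or below and the others at 5.38 or above. Tumor 4, of the first series, lay at -13.3, but tumor 3 and 5, of other series, lay at -11.3 and -12.2.

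**Figure D1:**
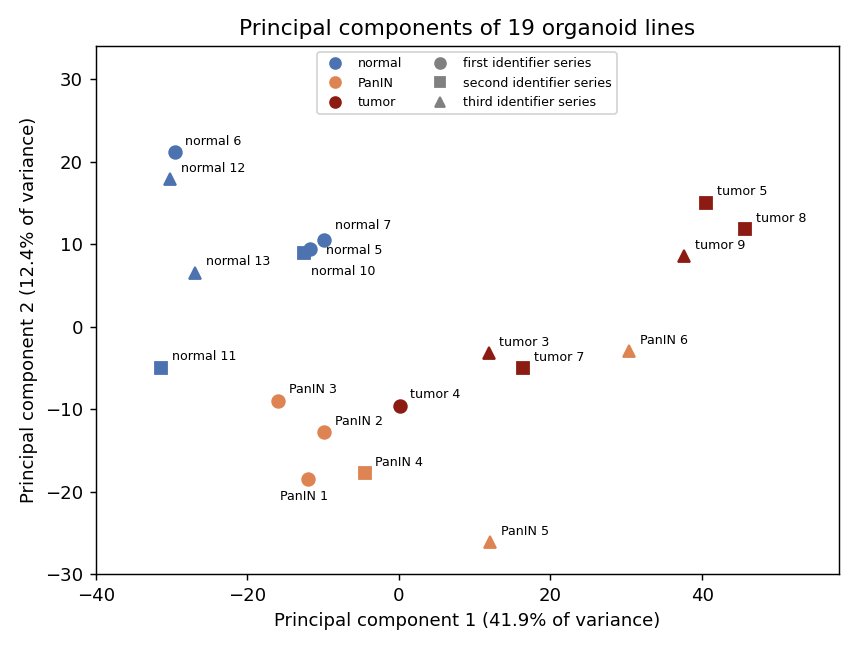
Principal components of log2(TPM + 1) over 12500 tested genes; each point is 1 organoid line, colour gives the group and shape the series of the library identifier, and the axes are component scores with their percent of variance. PanIN 6 lies at 30.4 on the first component, beyond tumor 3, 4 and 7.

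Trp53, altered in the mice with tumors, had a TPM of 67.7 ± 8.44 (SD, n = 7) in normal and 62.0 ± 12.5 (SD, n = 6) in PanIN lines. In tumor lines it stood at 69.8 ± 10.2 (SD, n = 6), and it passed no test in the main fit. The altered allele carries a point mutation, so the TPM of this gene did not check the genotype. Cdkn2a, which encodes the p16 and p19 tumor suppressors, rose from 55.0 ± 8.26 (SD, n = 7) in normal to 99.7 ± 18.7 (SD, n = 6) in tumor lines (adjusted p = 0.000617, limma). PanIN lines stood at 74.2 ± 16.2, which was called against neither group in the main fit, but against normal lines in 4 of 32 other settings. Smad4 (adjusted p = 0.468, tumor vs normal) and Cdkn2b (adjusted p = 0.0674, tumor vs PanIN) were called in no comparison of the main fit. Between tumor and PanIN lines, Cdkn2b was called in 4 of the 32 other settings, and Smad4 and Trp53 in 1 each.

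Between normal and PanIN lines Gcnt3, a glycosyltransferase that branches mucin glycans, rose 15.5-fold from 7.38 ± 4.75 TPM (SD, n = 7) to 120.3 ± 51.4 (SD, n = 6; log2 change 3.96, SE 0.35, adjusted p = 3.40e-06, limma). S100a7a rose 7.77-fold, Acsm3, a medium-chain acyl-CoA synthetase, 6.18-fold, and Agr2, a disulfide isomerase of mucus-secreting cells, 4.57-fold. Phgr1, Plac9, the hydroxysteroid dehydrogenase gene Akr1c14, the drug efflux pump gene Abcb1b and the imprinted gene Peg3 rose 3.97-fold, 3.32-fold, 3.12-fold, 3.05-fold and 2.98-fold. Gc, which encodes the vitamin D-binding protein, was 12.8-fold lower, at 25.1 ± 26.9 TPM against 294.9 ± 213.0 (log2 change -3.67, SE 0.62, adjusted p = 0.00135, limma). The matrix protease gene Mmp7 was 4.05-fold lower, from 1096 ± 312 to 301.3 ± 146.5 TPM. Pcp4l1, Pilrb1, Crp, Tnfrsf11b, Ildr2, the epithelial transcription factor gene Elf5 and the complement regulator gene C4bp were 3.99-fold, 3.79-fold, 3.66-fold, 3.53-fold, 3.40-fold, 3.34-fold and 3.27-fold lower. Pilrb1 belongs to a family of near-identical copies that can share reads, so its value is uncertain.

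Targets of p53 were higher in PanIN lines. Of 33 tested targets, 14 rose and 0 fell, or 22 and 1 adjusted over the list alone (camera adjusted p = 2.30e-16). With an estimated correlation the list was not called (adjusted p = 0.0892 with an estimated correlation). Gdf15, a stress-induced cytokine, rose 2.32-fold from 19.8 ± 4.82 (SD, n = 7) to 47.4 ± 11.8 TPM (SD, n = 6). Mdm2, the ubiquitin ligase of p53, rose 1.57-fold, Perp, a desmosome component, 1.63-fold, Dcxr 1.65-fold and Psrc1 1.57-fold. The median log2 change of the list was 0.38 over all lines and 0.28, 0.55 and 0.40 within the first, the second and the third identifier series.

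Transcripts known to follow MAPK signalling were also higher: 7 of 29 rose and 0 fell, or 11 and 1 adjusted over the list alone (camera adjusted p = 8.11e-07; adjusted p = 0.323 with an estimated correlation). Tgfa, an EGF receptor ligand gene, rose from 40.6 ± 7.44 to 82.4 ± 17.1 TPM, Ccnd1 (cyclin D1) 1.64-fold, the chromatin protein gene Hmga2 2.26-fold and Emp1 2.70-fold. The medians within the 3 series were 0.20, 0.41 and 0.37.

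In the list of NRF2 and glutathione genes, 11 of 34 rose and 0 fell, or 15 and 0 adjusted over the list alone (camera adjusted p = 4.32e-11; adjusted p = 0.0892 with an estimated correlation). Gstp1 and Gstm1, glutathione transferase genes, rose 2.27-fold to 1775 ± 495 TPM and 2.94-fold to 348.6 ± 104.7, and Gsto1 and Nqo1 rose 1.58-fold and 1.79-fold. Of 28 xenobiotic and aldehyde metabolism genes, 11 rose and 2 fell, or 13 and 4 adjusted over the list alone (camera adjusted p = 2.22e-06; adjusted p = 0.293 with an estimated correlation). Aldh1a1 rose 2.85-fold and Aldh2 1.61-fold. Reads of Gstp1 and Gstm1 can be shared with close paralogs. Among 35 oxidative phosphorylation genes 0 rose and 0 fell, also adjusted over the list alone, while 33 were higher by a median log2 change of 0.083 (camera adjusted p = 5.57e-05; adjusted p = 0.514 with an estimated correlation; adjusted p = 0.184 with fry).

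Of 16 tested gastric and mucin genes, 3 rose and 0 fell, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.00102; adjusted p = 0.293 with an estimated correlation). The risers were Agr2, Vsig1 (2.40-fold, to 2.40 ± 1.38 TPM) and the fucosyltransferase gene Fut2 (1.64-fold). The call of Fut2 was lost in 7 of the 19 fits that left out 1 line (highest adjusted p = 0.0790, without PanIN 5).

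In the cytokine list, 4 of 28 genes fell and 1 rose in PanIN lines, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.00460; adjusted p = 0.493 with an estimated correlation; 0.0559 with fry; camera adjusted p = 0.110 without normal 11 and PanIN 6). Il1rn, the interleukin-1 receptor antagonist gene, was 2.39-fold lower and Tgfb2 1.97-fold lower, while Cxcl15 rose 1.86-fold to 1.42 ± 0.578 TPM. In the interferon response list 3 of 24 fell and 0 rose, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.00222; adjusted p = 0.493 with an estimated correlation; 0.0663 with fry; camera adjusted p = 0.125 with a filter at a TPM of 5), among them Parp14 (1.63-fold lower) and the RNA sensor gene Ifih1 (1.41-fold lower). Of 19 MHC class I presentation genes, 3 fell and 0 rose, or 6 and 0 adjusted over the list alone (camera adjusted p = 0.00865; adjusted p = 0.473 with an estimated correlation). The peptide transporter gene Tap2 was 1.53-fold lower. Matrix and invasion genes went both ways, with 4 rises and 7 falls among 30, or 5 and 8 adjusted over the list alone, and the list was not called (camera adjusted p = 0.865). Timp1 and the collagen gene Col4a1 were 2.28-fold and 2.27-fold lower, and Adam9 rose 1.47-fold.

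In all, 847 of 12500 genes were called between PanIN and normal lines, 387 higher and 460 lower. Leaving out PanIN 5 reduced the count to 495. With median-of-ratios scaling 531 of 939 calls were rises, against 387 of 847 as deposited. Every line of one group lay above every line of the other for 381 of the 12500 tested genes, while chance gives such a separation in 0.117% of genes. Within the identifier series, 845, 839 and 845 of the 847 genes had the direction of the pooled fit, but these lines had also made the calls.

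**Figure D2:**
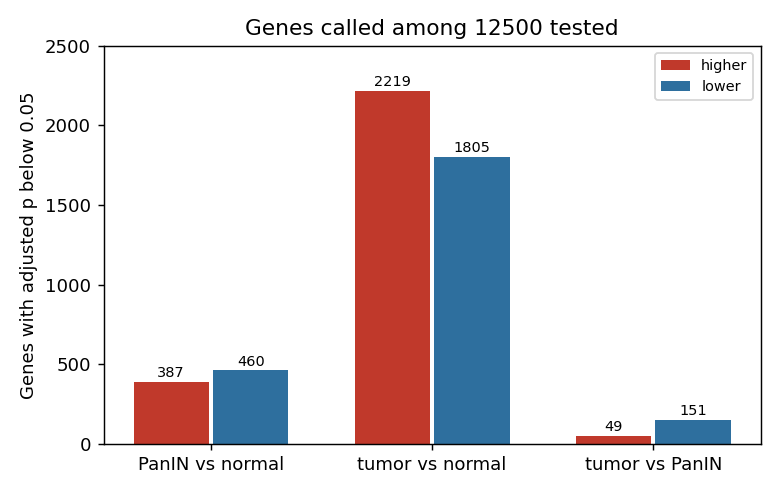
Number of genes with an adjusted p below 0.05 in each comparison, split into genes higher and lower in the first-named group; bars start at 0 and the counts stand above them. Tumor vs normal had 4024 calls, PanIN vs normal 847 and tumor vs PanIN 200.

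Between normal and tumor lines Agr2 rose 18.2-fold, from 0.781 ± 0.927 TPM (SD, n = 7) to 39.4 ± 33.0 (SD, n = 6; log2 change 4.19, SE 0.42, adjusted p = 8.47e-06, limma), Gcnt3 18.1-fold and Acsm3 14.4-fold. The water channel gene Aqp5 rose 6.38-fold, Park2 5.53-fold, the focal adhesion gene Tns4 5.28-fold, S100a7a 5.15-fold and Plac9 4.95-fold. Zscan4f, a gene known from cleavage-stage embryos, rose 5.42-fold, to 9.83 ± 3.63 TPM, and shares reads with near-identical family members. Gc was 45.5-fold lower, at 5.64 ± 5.55 TPM (log2 change -5.51, SE 0.62, adjusted p = 2.17e-05, limma). The complement gene C3 was 6.08-fold lower, Pilra 5.74-fold, the proteoglycan gene Bgn 5.67-fold and Mmp7 5.47-fold. Chi3l1, Pcp4l1, Casp12 and Akap12 were 4.66-fold, 4.44-fold, 4.38-fold and 4.28-fold lower.

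**Figure D3:**
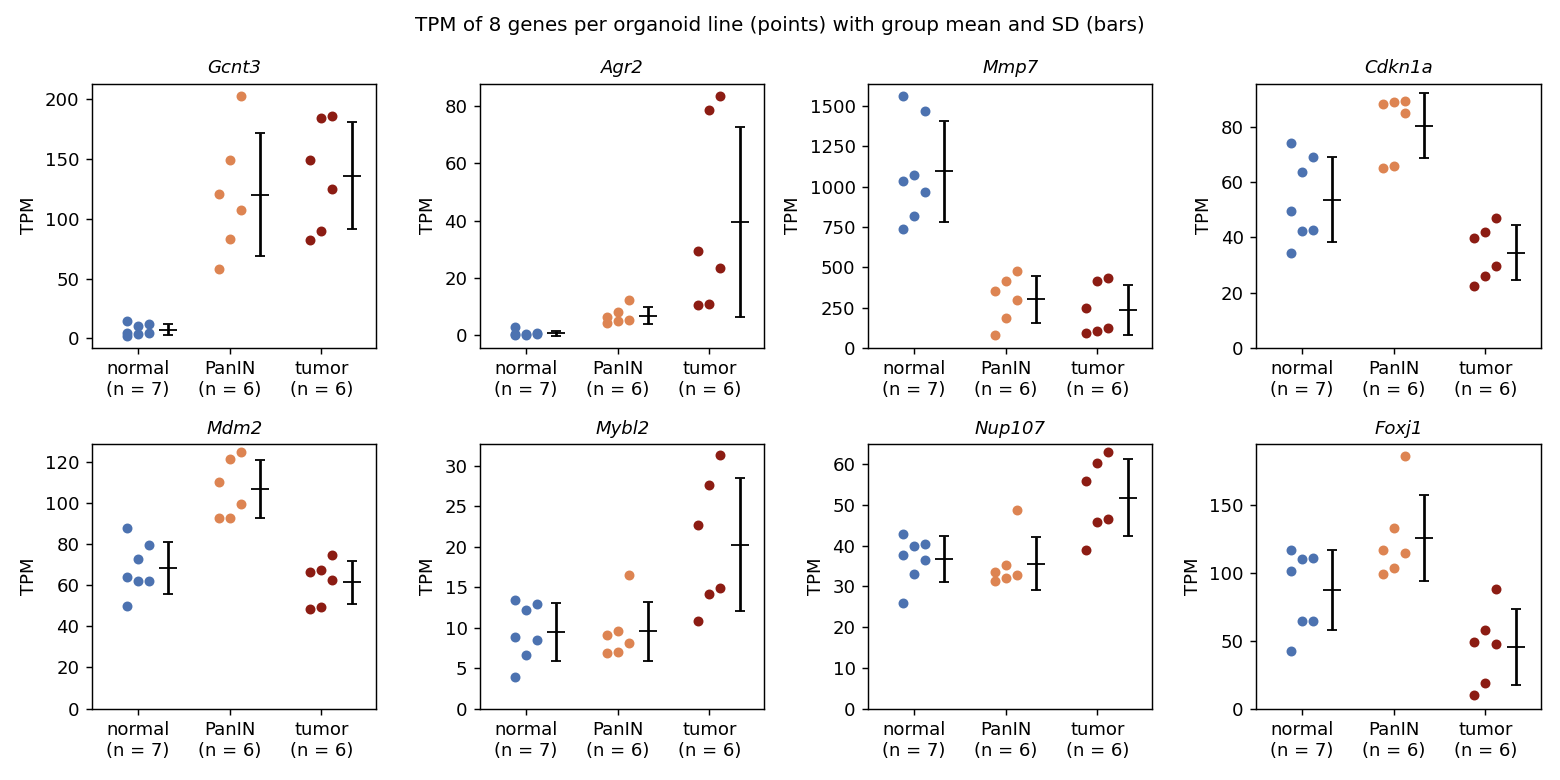
TPM of 8 genes in each organoid line; points are lines and the black bars beside them show the group mean and SD (normal n = 7, PanIN n = 6, tumor n = 6), with a separate linear axis for each gene. Gcnt3 stood at 7.38 ± 4.75 TPM in normal, 120.3 ± 51.4 in PanIN and 136.3 ± 44.9 in tumor lines.

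Of the gastric and mucin genes, 8 of 16 rose and 1 fell in tumor lines, with the same counts adjusted over the list alone (camera adjusted p = 0.00295; adjusted p = 0.323 with an estimated correlation). Besides Agr2, the secretory transcription factor gene Spdef rose 2.91-fold, Vsig1 4.58-fold and Fut2 2.11-fold. The medians within the 3 series were 1.17, 0.50 and 1.39. With a filter at a TPM of 5 the list was not called (camera adjusted p = 0.206). Among endoderm transcription factors, 3 of 18 rose and 2 fell, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.522); Foxa3 and Pdx1 rose 2.04-fold and 1.72-fold. The intestinal factor gene Cdx2 rose 3.47-fold, from 1.98 ± 1.02 to 10.8 ± 8.02 TPM.

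Cell cycle genes were higher in tumor than in normal lines, with 25 of 40 rising and 0 falling, or 36 and 0 adjusted over the list alone (camera adjusted p = 1.92e-07; adjusted p = 0.526 with an estimated correlation and 0.0549 with fry). E2f2 rose 2.10-fold, Mybl2 2.02-fold and the ribonucleotide reductase genes Rrm2 and Rrm1 1.92-fold and 1.65-fold. In the nucleoporin list 13 of 29 rose and 0 fell, or 17 and 0 adjusted over the list alone (camera adjusted p = 0.000131; adjusted p = 0.526 with an estimated correlation). Seh1l rose 1.33-fold, from 32.8 ± 3.42 to 44.0 ± 5.04 TPM, Nup160 1.42-fold and Nup37 1.46-fold. Neither rise was seen in the first series, where 1 tumor line stood against 3 normal lines: the median log2 change was -0.28 for cell cycle genes and -0.10 for nucleoporins there, 1.12 and 0.50 in the second series and 0.69 and 0.28 in the third. Normal 11 had a cell cycle score of -1.10, the lowest of the 19 lines.

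**Figure D4:**
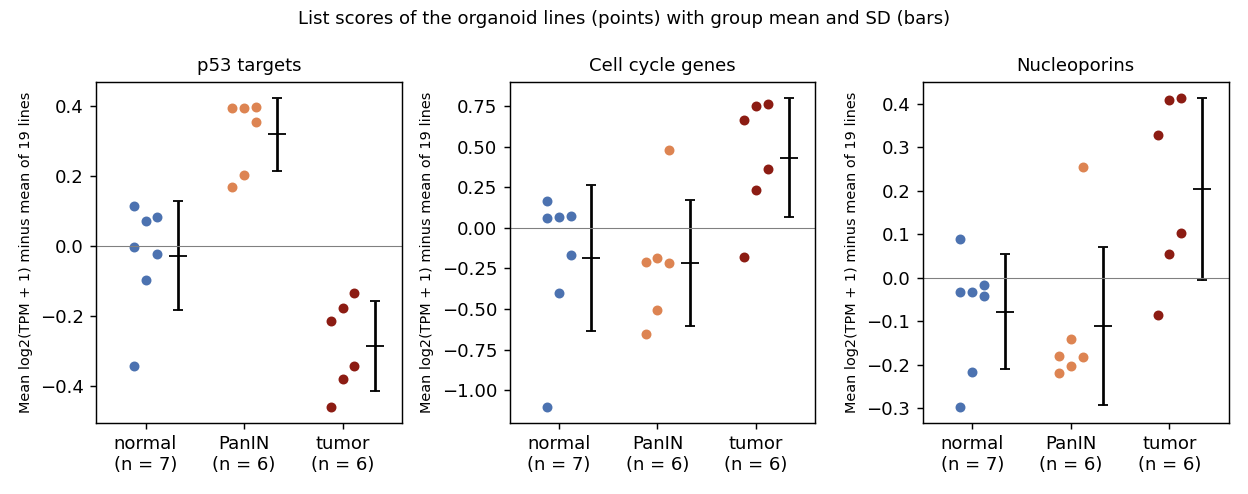
Scores of p53 targets, cell cycle genes and nucleoporins per organoid line, as mean log2(TPM + 1) minus the mean of the 19 lines; points are lines and black bars the group mean and SD (normal n = 7, PanIN n = 6, tumor n = 6). PanIN 6 stood at 0.48 for cell cycle genes and 0.25 for nucleoporins, the highest of the PanIN lines in both, and at 0.35 for p53 targets, above all tumor lines.

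Of the oxidative phosphorylation genes, 18 of 35 rose and 1 fell, or 21 and 1 adjusted over the list alone (camera adjusted p = 6.40e-05; adjusted p = 0.514 with an estimated correlation). Cyc1 rose 1.47-fold and Sdhd 1.29-fold, and Ndufa1 was 1.27-fold lower. This list was not called after quantile normalization (camera adjusted p = 0.141). Of the NRF2 and glutathione genes, 11 of 34 rose and 3 fell, or 15 and 3 adjusted over the list alone (camera adjusted p = 0.0153; adjusted p = 0.493 with an estimated correlation; camera adjusted p = 0.135 after quantile normalization). Gsr rose 1.62-fold and G6pdx 1.42-fold. MAPK output genes went both ways, with 9 rises and 4 falls among 29, or 10 and 5 adjusted over the list alone, and the list was not called (camera adjusted p = 0.143); Emp1 rose 3.38-fold, Hmga2 2.25-fold and Etv5 1.80-fold.

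Of 28 cytokine genes, 15 fell and 2 rose in tumor lines, or 17 and 2 adjusted over the list alone (camera adjusted p = 4.98e-06; adjusted p = 0.343 with an estimated correlation). Il1rn was 2.52-fold lower, at 33.4 ± 4.57 TPM against 88.1 ± 27.3, Tgfb2 2.43-fold, Pdgfb 2.21-fold and the chemokine gene Cxcl16 1.82-fold. The cytokine medians were 0.011, -0.80 and -0.99 in the 3 series. In the matrix and invasion list 12 of 30 fell and 3 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.00717; adjusted p = 0.473 with an estimated correlation), among them the laminin gene Lamb3 (1.99-fold lower) and the integrin gene Itgb6 (1.97-fold lower). In the interferon response list 6 of 24 fell and 2 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0113; adjusted p = 0.526 with an estimated correlation). This list was not called in 5 of the 34 settings, among them fry (adjusted p = 0.1197), rescaling without the 11 rows (camera adjusted p = 0.0770), a filter at a TPM of 5 and quantile normalization. MHC class I presentation genes had 8 falls and 1 rise among 19, with the same counts adjusted over the list alone, but the list was not called (camera adjusted p = 0.0648). B2m, the invariant chain of MHC class I, was 1.94-fold lower, at 338.5 ± 112.2 against 640.3 ± 145.6 TPM, Psmb8 2.81-fold and Tap2 1.94-fold.

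Ductal genes were lower too, with 8 falls and 1 rise among 29, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.00299; adjusted p = 0.384 with an estimated correlation). The keratin gene Krt8 was 1.79-fold lower, from 3393 ± 784 to 1873 ± 236 TPM, the bicarbonate transporter gene Slc4a4 2.81-fold and Clu 2.83-fold, while Aqp5 rose. Of the p53 targets, 9 of 33 fell and 2 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.00292; adjusted p = 0.493 with an estimated correlation and 0.0559 with fry): the death receptor gene Fas was 2.27-fold lower, Plk2 1.69-fold and Eda2r 1.56-fold. Cdkn1a, which encodes the cell cycle inhibitor p21, was 1.54-fold lower, and its call was lost without tumor 8 (adjusted p = 0.0543). Immediate early and heat shock genes had 8 falls and 1 rise among 21, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.0188; adjusted p = 0.473 with an estimated correlation), and the list was not called without tumor 7 (camera adjusted p = 0.0536).

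In all, 4024 genes were called between tumor and normal lines, 2219 higher and 1805 lower. The count was 2652 without tumor 8. Rises made up 55.1% of the calls as deposited and 37.4% after rescaling without the 11 rows, a share that thus depended on these rows, which took 16.3% and 18.2% of the TPM in tumor 5 and tumor 8. All lines of one group lay above all lines of the other for 908 of the 12500 tested genes (chance gives 0.117% of genes). Within the second and the third series, 4019 and 4018 of the 4024 genes had the direction of the pooled fit; within the first, where tumor 4 was the sole tumor line, 3148 did. These lines had also made the calls.

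Between tumor and PanIN lines p53 targets had the smallest p of all lists. Of 33 tested targets, 22 fell and 0 rose, or 26 and 0 adjusted over the list alone (camera adjusted p = 1.73e-27), and the list was called with an estimated correlation (adjusted p = 0.0301 with an estimated correlation). Cdkn1a was 2.35-fold lower, from 80.4 ± 11.7 (SD, n = 6) to 34.4 ± 9.88 TPM (SD, n = 6; log2 change -1.24, SE 0.19, adjusted p = 0.00289, limma). Eda2r, a TNF receptor family gene, was 2.48-fold lower, Gdf15 2.28-fold, Fas 2.17-fold, Dcxr 1.91-fold, Psrc1 1.86-fold, Mdm2 1.74-fold and the DNA repair gene Ercc5 1.61-fold. Every one of these 8 calls held in all fits that left out 1 line. The median log2 change of the list was -0.64, -0.83 and -0.44 within the 3 series, against -0.68 over all lines.

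Outside that list, Ano3, a gene of the anoctamin membrane protein family, was 3.97-fold lower in tumor lines, at 3.65 ± 2.37 against 16.2 ± 5.17 TPM, the carboxylesterase gene Ces2e 3.12-fold, the DNA repair gene Mgmt 3.03-fold and Zfp365 2.46-fold. Ces2e can share reads with its paralogs. Foxj1, the master regulator of motile cilia, and the kinesin gene Kif27 were 3.29-fold and 3.01-fold lower, with calls lost in 7 and 6 of the 19 fits that left out 1 line (highest adjusted p = 0.103 without tumor 8 and 0.0953 without PanIN 1). Among the genes that rose were Mecom, 1.86-fold, from 4.80 ± 1.12 to 10.1 ± 3.82 TPM, the lactate transporter gene Slc16a1 1.49-fold, Stk39 1.46-fold, Add3 1.37-fold, Chchd7 1.33-fold, Ccdc115 1.31-fold, Pstk 1.29-fold, Helb 1.28-fold, and Paip2b and Gabpb2 1.26-fold each. These 10 calls were lost in 1 (Add3, without PanIN 4, adjusted p = 0.0558) to 14 (Helb) of the 19 fits.

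In the gastric and mucin list 3 of 16 rose and 0 fell, or 4 and 0 adjusted over the list alone, and the list was not called (camera adjusted p = 0.133). Spdef rose 2.62-fold, from 0.243 ± 0.169 to 2.53 ± 1.75 TPM. It passed the filter in only 13 of the 19 fits that left out 1 line, and its call was lost in 0 of these 13. Agr2 and Anxa10 rose 3.98-fold and 2.35-fold, with calls lost in 7 and 11 of the 19 fits (highest adjusted p = 0.0947 without PanIN 1 and 0.119 without tumor 5). In the matrix and invasion list 2 of 30 fell and 0 rose, or 9 and 1 adjusted over the list alone (camera adjusted p = 6.19e-05; adjusted p = 0.338 with an estimated correlation and 0.0559 with fry). In the xenobiotic list 1 of 28 fell, the epoxide hydrolase gene Ephx1 (1.82-fold lower), and 0 rose, or 5 and 1 adjusted over the list alone (camera adjusted p = 1.47e-05; adjusted p = 0.323 with an estimated correlation).

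For cell cycle genes the fit over all genes called 0 of 40 between tumor and PanIN lines, and 39 rose and 0 fell adjusted over the list alone (camera adjusted p = 2.01e-11; adjusted p = 0.493 with an estimated correlation). For nucleoporins it called 0 of 29, and 21 rose and 0 fell adjusted over the list alone (camera adjusted p = 2.47e-07; adjusted p = 0.473 with an estimated correlation). All 40 cell cycle genes and 28 of the nucleoporins were higher in tumor lines, with median log2 changes of 0.65 and 0.29. Without PanIN 6, 38 cell cycle genes and 20 nucleoporins were called over all genes, all of them higher. The medians within the 3 series were 0.29, 0.82 and 0.30 for cell cycle genes and 0.12, 0.45 and 0.18 for nucleoporins.

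Camera also called 4 further lists lower in tumor than in PanIN lines, each with at most 1 gene called over all genes. They included duct genes (0 calls, or 0 rises and 2 falls adjusted over the list alone; camera adjusted p = 0.00139; adjusted p = 0.351 with an estimated correlation and 0.0827 with fry) and cytokines (0 calls, and 0 adjusted over the list alone; camera adjusted p = 0.000226; adjusted p = 0.454 with an estimated correlation and 0.123 with fry). NRF2 and glutathione genes had 0 calls, or 0 rises and 2 falls adjusted over the list alone (camera adjusted p = 0.00697; adjusted p = 0.473 with an estimated correlation and 0.225 with fry; 0.0746 by camera without PanIN 5). MAPK output genes had 1 fall, Ccnd1, whose call was lost in 5 of the 19 fits that left out 1 line (highest adjusted p = 0.101, without PanIN 4), or 2 rises and 6 falls adjusted over the list alone (camera adjusted p = 0.0188; adjusted p = 0.526 with an estimated correlation and 0.431 with fry). The MAPK list was not called in 8 of the 34 settings, among them the fits without tumor 7 (camera adjusted p = 0.128), tumor 3 or PanIN 5. Cholesterol synthesis genes were called higher, with 0 calls over all genes and 2 rises and 0 falls adjusted over the list alone (camera adjusted p = 0.0344; adjusted p = 0.751 with an estimated correlation and 0.179 with fry). This list was not called in 11 of the 34 settings, among them the fits without PanIN 6 (camera adjusted p = 0.122), PanIN 3, PanIN 4, tumor 4 or tumor 5. Of the other lists called, interferon response between tumor and normal lines was lost in 5 settings. Interferon response and cytokines between PanIN and normal lines, and NRF2 and glutathione genes in both tumor comparisons, were lost in 4 each. Oxidative phosphorylation between PanIN and normal lines and leukocyte genes between tumor and normal lines were lost in 3 each, and every further list in at most 2.

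In all, 200 genes were called between tumor and PanIN lines, 49 higher and 151 lower, and 3713 had an unadjusted p below 0.05. This count rested on single lines. It was 2833 without PanIN 6, 2397 without tumor 4, 789 without normal 11 and 393 without tumor 7. It was 114 without normal 13, 82 without PanIN 2, 77 without PanIN 3, 68 without tumor 5, 66 without tumor 9, 54 without PanIN 4, 53 without PanIN 1 and 51 without tumor 8. With the identifier series in the fit it was 65, and with weights per line 4889. The balance of rises and falls turned over in some of these fits, with 1983 rises and 850 falls without PanIN 6, 1660 and 737 without tumor 4, 516 and 273 without normal 11, and 3290 and 1599 with weights per line. Within each of the 3 series all 200 genes had the direction of the pooled fit, but these lines had also made the calls.

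Of the 847 genes called between PanIN and normal lines, 656 (77.4%) were called in the same direction between tumor and normal lines, 266 higher and 390 lower in both, and 5 in the opposite direction. Independent lists of these sizes would share 68.7 higher and 66.4 lower genes. Both comparisons used the same normal lines. In 100 simulations of unchanged groups the overlap was 0 at the same threshold. Unchanged groups give few or no calls at that threshold, so this 0 decides nothing about the 656. At an unadjusted p below 0.05 the simulations gave a mean of 121.8 shared genes, against 1660 observed. Among 99 other splits of all lines the overlap reached 2019 at this threshold, so the excess over that mean does not exclude chance. With the normal lines split into 3 and 4, one part per comparison, the overlap had a median of 231.5 over 70 splits (range 81 to 443). Without PanIN 5 the overlap was 400. Log2 changes of the 12500 genes, which are not independent replicates, correlated with r = 0.743, against a simulated mean of 0.427 (range -0.239 to 0.892). Their covariance was 0.0979, against a simulated mean of 0.0121 and a simulated maximum of 0.0461, and it was 0.0884 in the median split.

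The spread of lines around the other lines of their group did not differ detectably between groups. Its mean was 0.283 ± 0.0289 (SD, n = 7) in normal, 0.272 ± 0.0748 (SD, n = 6) in PanIN and 0.295 ± 0.0380 (SD, n = 6) in tumor lines on the log2 scale. The adjusted p was 0.764 for all 3 comparisons (exact two-sided permutation test, adjusted over 3).

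Most listed markers of other cell types stayed low. Of 24 acinar genes 22, of 22 endocrine genes 22, of 18 fibroblast and stellate genes 16, of 12 endothelial genes 10 and of 4 erythroid genes 4 stayed below a TPM of 1 in every line, as did 10 of 18 leukocyte genes, 7 of 10 tuft cell genes and 8 of 14 intestine and liver genes. The highest acinar value was 2.36 TPM (Cela1) and the highest endocrine value 0.54 (Insm1). Other lists held abundant genes: Cd14 (leukocyte) reached 450.2 TPM, Ttr (intestine and liver) 135.6, Ptgs1 (tuft) 90.5, Pdpn (fibroblast) 86.1 and Egfl7 (endothelial) 22.4. Which cells expressed these genes was not measured. Pdpn, on the fibroblast list, was 2.96-fold lower in PanIN lines, at 21.3 ± 12.7 against 56.2 ± 16.6 TPM in normal lines. The 6 tested leukocyte genes were lower in tumor than in normal lines, 2 of them called over all genes and also adjusted over the list alone (camera adjusted p = 0.00819; adjusted p = 0.338 with an estimated correlation). The most abundant of them, Cd14, had 342.9 ± 69.8 TPM in normal, 242.2 ± 36.1 in PanIN and 157.6 ± 51.3 in tumor lines.

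The authors' deposited table called 863 genes higher and 772 lower between PanIN and normal lines, 2695 and 2722 between tumor and normal lines, and 641 and 823 between tumor and PanIN lines at an adjusted p below 0.05. The authors' deposited table also called 818 of the 847, 3914 of the 4024 and 198 of the 200 genes called here. All 847, 4022 and 200 of these genes that had a value in the authors' deposited table had the same direction there. Among the genes tested here the authors had called 1310, 4590 and 1435. Most of their 1435 calls between tumor and PanIN lines were thus not called here. Both sets of calls came from the same lines, so their overlap is not independent support.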

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

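All tests of the 3 patterns below, of cycling cells, a wrong label, series and rescaling, were chosen only after the patterns were seen. For the series and the count of tumor vs PanIN genes, the bound was written before its value was computed, and splits of the lines were a planned kind of test.

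In 22 of 507 groups of lines, 1 line lay far from the others of its group relative to the range of the group. Chance gives this in about 1 in 20 groups. These were 18 of 408 groups for named genes, 3 of 72 for list scores, 1 of 18 for genotype genes and 0 of 9 for summaries per line. PanIN 6 was the line apart 8 times, and PanIN 3 and normal 10 were so 3 times each. All gene values in the next paragraph are log2(TPM + 1).

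PanIN 6 stood above the other PanIN lines for the nucleoporin score (0.2544), Mybl2 (4.13), Nup160 (4.465), Nup107 (5.636) and Ildr2 (2.167). It stood below them for Slc4a4 (2.753), Ugt1a7c (4.588) and B2m (8.593). PanIN 3 stood above for the basal and squamous score (0.7764), Fn1 (4.505) and Itgb6 (5.045). PanIN 5 stood below for Il23a (0.2016). Among the normal lines, normal 10 stood above for Acsm3 (1.007) and below for Kif27 (2.799) and Zfp365 (2.087). Normal 6 stood above for Agr2 (1.934) and Chi3l1 (4.655), normal 12 for Trp53 (6.423) and normal 13 for Anxa10 (1.299). Among the tumor lines, tumor 5 stood below for Tgfa (5.319) and Aldh2 (5.708), and tumor 7 for the score of genotype genes (-0.2545).

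The difference between tumor and PanIN lines itself differed between the sexes for 1207 genes (interaction term, limma). Among female lines 3561 genes were called, 2455 higher and 1106 lower in tumor lines, and among male lines 3 were called. The cell cycle median was 1.04 in females and 0.24 in males, while the p53 target median was -0.63 and -0.55. With the cell cycle score in the fit, the interaction was called for 945 genes. Of 100 splits by sex within the groups, 1 gave as many genes, the real split itself, and the highest other gave 825. Such a rank argues against chance but does not exclude it, and the splits took no account of the identifier series. The female PanIN lines were all in the first identifier series and the male ones in the second and the third, and PanIN 6 is male, so sex and series cannot be told apart here among the PanIN lines. The female tumor lines were all in the second and the third series. Among females the difference between tumor and PanIN lines therefore cannot be told apart from a difference between series. Between tumor and normal lines the interaction was called for 2 genes, Chchd8 and Liph (adjusted p = 0.0312 each, limma). Between PanIN and normal lines it was called by limma for 0 genes, with 712 at an unadjusted p below 0.05.

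The first pattern weighed was the small number of genes called between tumor and PanIN lines with PanIN 6 in the fit. A mislabelled sample is argued against by its p53 target score, 0.354, against at most -0.13 in any tumor line (SD of the tumor lines 0.128). Other values went the other way: PanIN 6 correlated with tumor 9 (r = 0.986), tumor 8, tumor 7 and tumor 3 more than with any PanIN line (highest 0.979, PanIN 5), and its cilia score, -0.376, lay within the range of the tumor lines. The p53 score thus argues only against a tumor line with p53 target values like those of the 6 measured here, and it does not exclude another kind of tumor line. A difference between library series is argued against as the whole cause, since with the series in the fit 65 genes were called with PanIN 6 and 2090 without it. A difference in the share of cycling cells cannot be told apart by the test run: with the cell cycle score in the fit 14 genes were called, against 200, but without PanIN 6 such a fit by limma called 0, so the count with the score decides nothing here. More cycling cells in PanIN 6, for technical or biological reasons, and the sex of the lines stay open.

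The second pattern was that p53 targets were higher in PanIN lines and lower in tumor lines. The median log2 change between tumor and PanIN lines, -0.68 (SD over the targets 0.46), was -0.62 (SD 0.48) with the difference between library series in the fit and -0.75 (SD 0.47) after rescaling for a few transcripts taking part of the TPM. With the share of cycling cells in the fit, as the cell cycle score, it was -0.60 (SD 0.42). The number of targets called then fell from 22 to 7, as the changes became smaller and their median SE went from 0.130 to 0.153. The tests of the series and of rescaling argue against their explanations as the whole cause of the difference between tumor and PanIN lines. The test of cycling cells argues against them as the whole cause of that difference only as far as the score captures their share, which was not measured. A candidate explanation for that difference is the Trp53 R172H allele, a hypothesis that the tissue of origin, which differs in the same way, leaves open. Normal and PanIN lines both lack this allele, so it does not account for the rise between them (median log2 change 0.38). Between tumor and normal lines the median was -0.19.

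The third pattern was that nucleoporins were higher in tumor lines. The cell cycle score stood in for the share of cycling cells, which was not measured. With it in the fit, the median log2 change between tumor and PanIN lines was 0.081 (SD over the list 0.10), against 0.29 (SD 0.17) before. Most of the difference in nucleoporins thus went with the cell cycle score, although camera still ranked the list above other genes in that fit. The cell cycle and nucleoporin scores moved together so closely that this fit cannot tell cycling cells from another shared cause. Across the 19 lines, the cell cycle and nucleoporin scores correlated with r = 0.937 (permutation p = 1e-05, the smallest it can give, adjusted 1e-05 over 3 relations) and rho = 0.965 (permutation p = 1e-05). Without normal 11 and PanIN 3 r was 0.974, within the series it was 0.883, 0.943 and 0.969, and within normal, PanIN and tumor lines 0.922, 0.886 and 0.978 (exact permutation p = 0.00198, 0.0542 and 0.00139). Within PanIN lines rho was 0.314 (exact permutation p = 0.564), so the ranks of these lines did not show the relation.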

How the results depend on the processing

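The identifier series as a covariate, the rescaling without the 11 transcripts and the fit without normal 11 and PanIN 6 were chosen after seeing the data. For calls in the order PanIN vs normal, tumor vs normal, tumor vs PanIN and overlap of the first 2, leaving out 1 line gave 495 (without PanIN 5) to 894 (without tumor 5), 2652 (without tumor 8) to 4856 (without tumor 4), 51 (without tumor 8) to 2833 (without PanIN 6) and 400 (without PanIN 5) to 686 (without PanIN 3). A 2-fold minimum gave 189, 460, 43 and 145. A filter at a TPM of 5 gave 535, 130 for tumor vs PanIN and an overlap of 415. The replicate block gave 258, 225, 8 and 127. The line numbers do not pair the lines: 7 same-numbered pairs correlated with a median r of 0.0707, and 1 of 11 lines correlated best with its own number. For tumor vs PanIN alone, fits of only the 2 groups gave 97, no filter 93, quantile normalization 333, weights per line (arrayWeights) 4889 and the identifier series as a covariate 65. Leaving out normal 11 and PanIN 6 together gave 3015 and an overlap of 419, and normal lines split into 3 and 4 gave a median overlap of 231.5. A stricter filter and a 2-fold minimum leave fewer genes by construction; for the other settings the cause was not tested. The number of lists called was 31, and 1 with a correlation estimated from the data, 21 with fry. No list called turned its direction in any setting, and the p53 targets between tumor and PanIN lines were called in all 34.

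Genes that reversed were not called in either fit. Trp53 between tumor and normal lines, 0.040 on the log2 scale, was -0.078 after quantile normalization, -0.050 after rescaling and -0.024 to 0.099 when 1 line was left out (lowest without tumor 8). Between PanIN and normal lines it was -0.14, and 0.041 with the replicate block. Smad4 between tumor and normal lines, 0.064, was -0.027 after quantile normalization and -0.024 after rescaling. Planned count models (edgeR, DESeq2) were not run, since the values are TPM. Depth is unknown and sets no limit that can be given here.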

Other observations

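The tests of motile cilia, complement and Zscan4 genes and of whole chromosomes were chosen only after the data were seen. So were the splits for the overlap at an unadjusted p, the correlation after rescaling, and fry and the estimated correlation for these lists. The 3 lists named here were all those tried, and the other splits of the lines were planned.

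Genes of motile cilia were lower in tumor lines. Leaving out Foxj1 and Kif27, which had drawn attention to them, 23 members were tested: between tumor and normal lines 18 fell and 0 rose, with a median log2 change of -1.03 (camera adjusted p = 1.28e-08; adjusted p = 0.00275 with fry, but 0.145 with an estimated correlation, which ends the call). Rsph1, a radial spoke gene, had 10.0 ± 2.42 TPM (SD, n = 7) in normal, 10.2 ± 3.46 (SD, n = 6) in PanIN and 4.45 ± 1.64 (SD, n = 6) in tumor lines. Kif9, a kinesin gene, had 8.88 ± 1.72, 8.84 ± 3.54 and 3.27 ± 1.88 TPM. Between PanIN and normal lines 0 genes were called by limma and the list was not called (median -0.083, camera adjusted p = 0.209). Between tumor and PanIN lines 5 fell and 0 rose (median -0.77, camera adjusted p = 5.98e-11; 0.0119 with fry and 0.145 with an estimated correlation). Without PanIN 6, 16 fell and 1 rose (median -0.94), so this count rested on that line. With the series in the fit limma called 0 of them (median -0.65), and the medians within the 3 series were -0.52, -1.41 and -0.115. Medians within the 3 series, tumor vs normal, were -0.66, -1.04 and -1.13. As many as 13 of the 40 listed genes in the data stayed below a TPM of 1 in every line. Among them were Dnaic1, Dnaic2, Hydin and Ccno, with at most 0.1, 0.36, 0.11 and 0.19 TPM in any line. With the cell cycle score in the fit, the median between tumor and normal lines was -0.64 (SD over the list 0.27), against -1.03 before (SD 0.52), and 2 genes were called. The score is an RNA value and may not capture the whole share of cycling cells. What stayed in that fit therefore cannot decide whether cycling cells were the whole cause. A lower share of ciliated cells in tumor lines is another candidate explanation, which was not tested. Whether any line held ciliated cells was not measured.

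Gc, C3, Crp and C4bp had drawn attention to complement and acute-phase genes. Without these 4, 8 of 13 tested members fell between normal and tumor lines and 1 rose (median log2 change -1.28, camera adjusted p = 0.000291; adjusted p = 0.00832 with fry, but 0.152 with an estimated correlation, which ends the call). C3 had 176.5 ± 68.2, 71.6 ± 36.0 and 38.9 ± 31.9 TPM in normal, PanIN and tumor lines, Lcn2 2591 ± 693, 1414 ± 504 and 837.0 ± 694.6, and Cp 979.4 ± 242.9, 650.0 ± 193.7 and 376.2 ± 251.1. The riser, Cd55, had mean values of 5.99, 15.1 and 8.92 TPM. Between PanIN and normal lines 2 fell and 1 rose, and the list was not called (camera adjusted p = 0.251). Zscan4f had drawn attention to Zscan4 and cleavage-stage genes. The 7 other tested members all rose between normal and tumor lines, with a median log2 change of 1.45, and 2 of them rose in PanIN lines. These genes include near-identical copies that can share reads with Zscan4f, so no p is given for the list.

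The hypothesis that a line had gained or lost a chromosome in most cells was tested with 8997 genes, of which 86.62% had a chromosome by symbol in the mouse GRCm38 gene table. The largest absolute median deviation of a chromosome was 0.105, in tumor 8, against a bound of 0.3 set after the data were seen and 0.585 for 3 copies in every cell. This argues against a gain or loss of a chromosome in most cells of any of the 19 lines and leaves smaller shares of cells open.

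Each count was compared with 100 splits of the lines, the real one included. For genes changed between PanIN and normal lines 1 split gave as many, the real one with 847, and the highest other gave 325. For genes changed between tumor and normal lines it was 1 split, with 4024 and a highest other of 1082, and for the overlap 1 split, with 656 and a highest other of 0. Only the real split reached either of the 2 counts of genes, which argues against chance for them at 1 of 100 splits each. For the overlap of calls the splits decide nothing, because 0 of the 99 other splits had a gene called by limma in both comparisons. At an unadjusted p below 0.05, 2 splits gave an overlap as large as the real 1660 genes, the real one included. The highest other gave 2019, above the real overlap, so this rank does not exclude chance at that threshold. For genes changed between tumor and PanIN lines 3 splits gave at least 200, the real one included. The highest other gave 4521, far above the real count, so this count does not exclude chance and points to a structure of the samples. For gene lists called 13 splits gave at least 31, the real one included. Each of the 99 other splits called lists, from 8 to 36, so chance cannot be excluded for the number of lists. A call by camera at the preset correlation was thus common in lines regrouped without regard to their labels. Such a call alone does not argue against chance.

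The cell cycle score was lower where the percent of TPM in the 11 transcripts without an authors' comparison was higher (r = -0.858, permutation p = 1e-05, the smallest it can give, adjusted 1e-05 over 3 relations; rho = -0.826, permutation p = 2e-05). Without normal 11 and PanIN 3 r was -0.880, and within the 3 series it was -0.712, -0.946 and -0.878 (exact permutation p = 0.0649, 0.00417 and 0.0347). TPM has a fixed sum, so a lower share in these transcripts raises every other gene and fixes part of this relation. With the score taken after rescaling without them, r was -0.821 (permutation p = 1e-05, adjusted 1e-05 over 3 relations) and rho -0.809 (permutation p = 3e-05), and within the series r was -0.673, -0.932 and -0.844 (exact permutation p = 0.0946, 0.00556 and 0.0486).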
